A study of Oryctolagus cuniculus with 12 samples.

How the data were processed

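Ventricles of fetal rabbit hearts were compared between fetuses with intrauterine growth restriction (IUGR), in which a fetus grows less than expected for its age, and control fetuses. The titles of the IUGR samples call them treatment, and what the treatment was is not reported here. Any other effect of such a treatment cannot be told apart from growth restriction. Per the labels' protocols, every sample contributed 500 ng of RNA, which was labelled with Cy3 dye and hybridised to an Agilent array of rabbit transcripts, with RNA integrity numbers from 9.3 to 9.9. Each of the 12 samples, 6 IUGR and 6 control, had 1 array of its own. The labels number the samples as 6 pairs of 1 IUGR and 1 control sample, and what the members of a pair share is not stated in the sources used here. The labels call the samples replicates without saying in words that each came from another litter, so p-values measure the spread between these pairs.

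The deposited values are log2 probe signals, and the authors processed them with RMA per the submitters' processing notes, which give no version. Base 2 was inferred from the values: the highest, 15.83, corresponds to 58146 on a linear scale, just under the ceiling of a 16-bit scanner. The sorted values of the 12 arrays differed by at most 0.13 log2 at any rank, so the arrays had already been brought to 1 distribution. That step removes any shift common to most transcripts, and differences are relative to the bulk of the probes. The scanner software, the background method and any filter on probes are not given in the sources used here, and detection and saturation flags were not used here. The table used here holds 43603 probes of the 43803 sequences that the labels mention. Values were used as deposited, with no further normalisation and no filter on dim probes. For arrays the number of pairs limits the precision: the median standard error of an IUGR minus control difference was 0.191 log2, with 0.137 for probes above the median level and 0.256 for probes below it.

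Gene symbols were available to the present work for 1673 probes, 3.84% of the table, and were updated through transcript accessions and synonyms to 591 genes, of which 562 have a symbol and 29 only a locus number. No probe had several symbols, and 41930 probes are unnamed here. Of the 591 genes, 343 had 2 or more probes. A gene was represented by the probe with the highest mean over all 12 arrays, chosen without regard to group, and the number of its probes with the same sign is given for named genes whose probes disagree. No genome came with the data, so no coordinates are given.

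Differences between IUGR and control were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with the pair as a fixed block, and p-values were adjusted by Benjamini and Hochberg over the 43603 probes with a threshold of 0.05. The numbers were checked to pair the samples: deviations from the group means correlated within each pair at 0.129 to 0.254, with a mean of 0.166 against -0.033 for arrays of different pairs, and all 6 IUGR and all 6 control arrays correlated best with their own partner. Centring on the group means pushes correlations between different pairs below 0 when those within pairs are above it. The value of -0.033 is therefore no separate baseline. The paired fit was also the fit set in advance, from the labels. Gene lists were tested with camera in limma (preset inter-gene correlation 0.01) where at least 5 members were measured, against all named genes, and adjusted over all lists tested. Of 49 lists fixed, 34 for processes and 15 for cell types, 7 reached 5 measured members and 14 had none. Beside camera, the same lists were tested with an estimated correlation, with fry, which tests whether the genes of a list move on balance in 1 direction, and with an exact two-sided test of the mean difference per pair over all 64 sign changes of the 6 pairs, whose smallest possible p is 0.03125.

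The genes named in the text follow a rule. Up to 10 per direction were to be those past the adjusted threshold with 1 sign in 6 of 6 pairs, filled with the genes of the smallest p among those with 1 sign in 6 of 6 pairs where too few passed. The 3 members with the smallest p of the 4 lists with the smallest camera p, and 24 genes of heart muscle, metabolism and growth, of which 7 were measured, were added. The groups, the lists, the tests, the rule and the alternatives of the sensitivity part were set before the data were examined. The fit was tested on simulated data with 200 changed probes among 43603. The noise was normal and independent between probes, with each probe's SD as moderated in the limma fit. Real arrays need not follow this, so the detection rates hold for the simulated data. At 6 pairs, it called 0 of 67 probes changed by 0.5 log2, 12 of 67 changed by 1 log2 and 50 of 66 changed by 2 log2, and it also called 4 unchanged probes. Without any simulated change, 1.00% of the probes had an unadjusted p under 0.01 and 2 probes were called.

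The alternatives were the fit without the block, the pair as a random block, leaving out each pair in turn, centring each array, quantile normalisation once more, leaving out dim probes, an intensity trend with a robust prior, array weights, an ordinary paired test, an adjusted threshold of 0.10, genes in place of probes, the mean of all probes of a gene, and for the lists an estimated correlation, fry and ranks. Correlations across the 12 arrays were tested by 100000 permutations, and those of differences within pairs by an exact test over the 720 orders of 6 pairs. The permutations exchanged all 12 arrays freely, as if independent. Arrays of a pair resembled each other, so the permutation p-values can be too small. Figures were drawn with matplotlib 3.10.9.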

Results

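The data set holds single-colour array measurements of 12 fetal rabbit heart ventricles, 6 with intrauterine growth restriction and 6 controls, matched in 6 pairs. The 43603 probe signals ran from 1.36 to 15.83 on the log2 scale, with a median probe mean of 4.61. Any 2 arrays correlated at 0.957 to 0.978 across probes, which are not independent replicates. The series' title concerns energy metabolism, and the labels give special attention to the sarcomere, the contractile unit of the heart muscle cell. Named genes are those of 1673 probes, and the lists for the respiratory chain, ATP synthase, the citric acid cycle and the mitochondrial ribosome had no named member, so they were not analysed here. Unless stated otherwise, differences are IUGR minus control in log2 units, as a mean ± SD over n = 6 pairs.

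The first question was which genes differ between growth-restricted and control ventricles. The most regular differences were small, and no gene passed the adjusted threshold. AKR1D1, a steroid reductase of bile acid synthesis, was higher in IUGR by 0.70 ± 0.41, a 1.63-fold difference with a level of 7.16 ± 0.46 against 6.46 ± 0.63. KDR, a receptor for vascular endothelial growth factor, was higher by 0.43 ± 0.30 (1.34-fold). HBA, the alpha chain of haemoglobin, was higher by 0.41 ± 0.31 (1.32-fold) at a level of 14.81 ± 0.34 against 14.41 ± 0.53. TREH, which splits trehalose, was lower, with a difference of -0.47 ± 0.36. Each of these 4 genes was chosen for having the same sign in 6 of 6 pairs, so that sign is no test of them, and each had a limma adjusted p of 0.982.

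Of the 591 genes, 13 were higher and 2 were lower in all 6 pairs, 2.54% of them, where chance gives 3.12%. The others named by this criterion were EDN2 (0.82 ± 0.68), a vasoconstrictor peptide, ARRB1 (0.31 ± 0.20), which ends receptor signalling, CLN3 (0.21 ± 0.17), a lysosomal membrane protein, SULT2A1 (0.83 ± 0.92), a sulfotransferase, SLC10A1 (0.58 ± 0.68), a bile acid transporter, GNRHR (0.34 ± 0.17), the receptor of gonadotropin-releasing hormone, TNFSF13B (0.54 ± 0.52), a B cell survival factor, and, lower in IUGR, CR1 (-0.74 ± 0.93), a complement receptor. None of them passed the adjusted threshold (limma adjusted p = 0.982 for each). Several lay low in signal: EDN2, SULT2A1, CR1, SLC10A1, TNFSF13B and GNRHR stood at percentiles 38.0, 34.8, 22.0, 19.9, 15.7 and 7.92 of the probe levels. For GNRHR 1 of 3 probes, for TNFSF13B 1 of 4, for SLC10A1 2 of 5, for SULT2A1 3 of 5 and for ARRB1 4 of 5 had the sign given here, against 3 of 3 for AKR1D1, HBA and CLN3. The dimmer probes had 1 sign in 5 and 6 pairs for AKR1D1, in 5 and 5 for HBA and in 4 and 5 for CLN3. With the mean of all their probes, the differences of GNRHR and TNFSF13B turned to -0.06 and -0.01, and those of SULT2A1, SLC10A1, ARRB1 and CLN3 shrank to 0.12, 0.19, 0.13 and 0.11. Leaving out 1 pair moved TNFSF13B to 0.34 and SLC10A1 to 0.33 (pair 1), SULT2A1 to 0.49 (pair 5) and CR1 to -0.39 (pair 6).

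**Figure D1:**
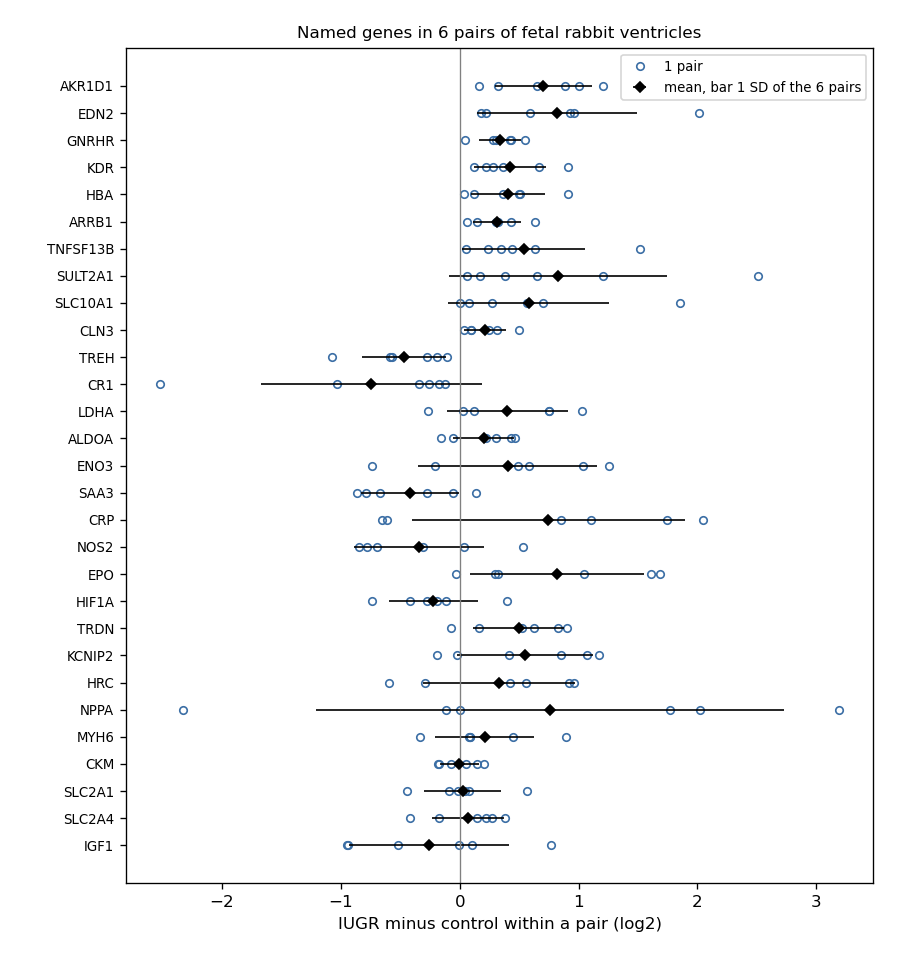
Each row is a gene named by the rule, and the horizontal axis gives the IUGR minus control difference in log2. Open circles are the 6 pairs, the diamond is their mean and the bar is 1 SD. The genes from AKR1D1 to CLN3 lie above 0 in all 6 pairs, TREH and CR1 lie below 0 in all 6, and NPPA spreads most widely, with an SD of 1.97.

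Across all probes, 0 of 43603 passed the adjusted threshold in limma (lowest adjusted p = 0.982), and the ordinary paired test also called 0. At an unadjusted p under 0.05 there were 1562 probes against 2180 expected by chance, and under 0.01 there were 224 against 436, of which 124 were higher and 100 lower in IUGR. The paired block raised that count, since the fit without it gave 111. Of the 224 probes, 183 had a mean level below the median probe. The same sign in 6 of 6 pairs was seen for 983 probes, 2.25%, where chance gives 3.12%. Among genes, 24 had an unadjusted p under 0.05, 14 higher and 10 lower, where 30 are expected by chance. With 6 pairs, changes of 0.5 log2 were not detectable in the simulated data, and 17.9% of changes of 1 log2 were called.

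The gene lists asked whether energy metabolism and other processes of the fetal heart shifted together. Glycolysis and glucose uptake had the smallest p: all 7 measured members were higher in IUGR, by 0.18 ± 0.24 on the mean, in 4 of 6 pairs. LDHA, the muscle-type lactate dehydrogenase, was higher by 0.40 ± 0.51 in 5 of 6 pairs and in 5 of its 5 probes. ENO3, an enolase, was higher by 0.40 ± 0.76 and ALDOA, an aldolase, by 0.20 ± 0.26, each in 4 of 6 pairs. The only ALDOA probe lay at 14.18 to 14.97, near the highest value of the table (15.83). ENO3 differed by 0.23 without pair 5 and by 0.63 without pair 3. The glucose transporters SLC2A1 and SLC2A4 differed by 0.02 ± 0.33 and 0.07 ± 0.31, and the sign of SLC2A1 turned without pair 5 (-0.08). SLC2A4 ran from 0.01 without pair 5 to 0.17 without pair 2. The list did not pass the threshold (camera adjusted p = 0.121, adjusted p = 0.347 with an estimated correlation, exact p = 0.125). It passed without pair 3 (adjusted p = 0.0417), with an intensity trend (adjusted p = 0.022) and with the mean of all probes of a gene (adjusted p = 0.043). Over its 18 alternatives the adjusted p ran from 0.022 to 0.381. Those calls used the preset correlation of 0.01, while the correlation estimated for this list was 0.171 on the main settings. None of the calls was tested with an estimated correlation in its own setting. In the sets of pairs 1 and 2, 3 and 4, and 5 and 6, whose arrays resembled each other, the mean difference of the list was 0.22, -0.07 and 0.40, and without pair 5 its mean over the pairs was 0.11.

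For creatine kinase and adenine nucleotide transfer, by which ATP energy is carried from mitochondria to the filaments, 6 of 7 measured members were higher in IUGR, with a mean of 0.10 ± 0.13, or 0.05 without SLC6A8, the creatine transporter. CKM, the muscle creatine kinase, differed by -0.01 ± 0.16, but its only probe lay at 15.44 to 15.80, close to the highest value of the table (15.83), where a difference is poorly measured. Its sign turned when pair 1, 3 or 4 was left out. The list did not pass (camera adjusted p = 0.206). Of the hypoxia response, 5 of 6 members were higher, by 0.21 ± 0.21 on the mean, in 5 of 6 pairs (exact p = 0.0625, camera adjusted p = 0.206). The mean was 0.09 without EPO, and LDHA and SLC2A1 are members of the glycolysis list as well. EPO, erythropoietin, differed by 0.82 ± 0.73 in 5 of 6 pairs with 1 probe, at a low level of 3.18 ± 0.71 against 2.36 ± 0.20. Its other probe gave 0.10, and the mean of both gave 0.46. HIF1A, the oxygen-regulated transcription factor, was lower, with a difference of -0.22 ± 0.38 and 3 of 3 probes of that sign, and it ran from -0.35 without pair 6 to -0.12 without pair 2. Without pair 5 the mean of the hypoxia list was 0.14.

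Calcium handling and excitation covered 16 measured genes, 10 higher and 6 lower, with a mean of 0.09 ± 0.11 and no call (camera adjusted p = 0.206). KCNIP2, a subunit of the transient outward potassium channel, was higher by 0.55 ± 0.57 in 4 of 6 pairs, and 5 of its 5 probes had that sign. TRDN, triadin of the calcium release complex, was higher by 0.50 ± 0.38 in 5 of 6 pairs, in 3 of 5 probes, and by 0.19 with the mean of all probes. HRC, a calcium-binding protein of the sarcoplasmic reticulum, was higher by 0.33 ± 0.64, with 0.20 without pair 6, 0.21 without pair 1 and 0.51 without pair 4. Without pair 5 the mean of the list was 0.06, as it was without KCNIP2 or without SLN, also an atrial marker. In pairs 3 and 4 the list differed by -0.01 and -0.06. The glycolysis list differed there by -0.11 and -0.04, and the creatine kinase list by -0.08 and -0.03. Each of these lists was highest in pair 5, so their upward means are not separate evidence. In pairs 3 and 4 KCNIP2 differed by -0.11 on the mean, against 0.74 in pairs 1 and 2 and 1.01 in pairs 5 and 6.

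**Figure D2:**
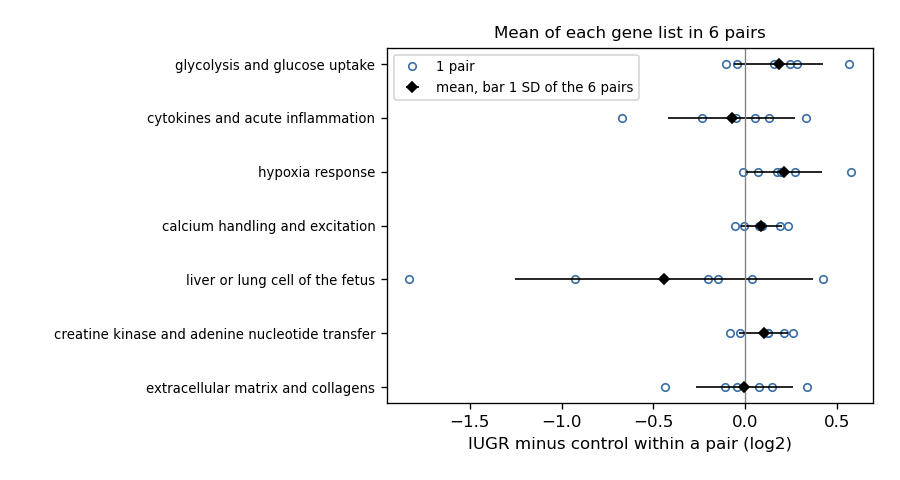
Each row is a tested gene list, and the horizontal axis gives the IUGR minus control difference of its mean in log2. Open circles are the 6 pairs, the diamond is their mean and the bar is 1 SD. Glycolysis and glucose uptake lies at 0.18 with 4 of 6 pairs above 0, and the liver or lung markers spread most widely, with an SD of 0.81.

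Of 17 measured cytokine and acute inflammation genes, 12 were lower in IUGR, with a mean of -0.07 ± 0.35 and 3 of 6 pairs each way. The mean turned to 0.05 without pair 6 and was -0.16 without pair 3, and it was -0.13 without CRP and -0.05 without TLR2. SAA3, an acute-phase protein, differed by -0.42 ± 0.41 (lower in 5 of 6 pairs), NOS2, the inducible nitric oxide synthase, by -0.34 ± 0.55 and CRP, C-reactive protein, by 0.75 ± 1.15, all at a level below the median probe. Probes disagreed for NOS2, with 3 of 5 lower, from -0.79 to 0.55, and a mean of -0.09, and for CRP, with 4 of 5 higher, from -0.14 to 0.75, and a mean of 0.22. Without pair 4 NOS2 differed by -0.52 and CRP by 0.49. The list did not pass (camera adjusted p = 0.206, adjusted p = 0.347 with an estimated correlation), with an adjusted p from 0.0417 without pair 3 to 0.716 without pair 6 over its 18 alternatives, and it also passed with the mean of all probes of a gene (adjusted p = 0.043). Neither call was tested with an estimated correlation in that setting. The 7 extracellular matrix genes differed by -0.01 ± 0.26 (camera adjusted p = 0.532), with a mean of 0.08 without pair 1 and above 0 also without pair 3 or 4. Markers of fetal liver or lung, which a heart sample could hold as admixed RNA, gave -0.44 ± 0.81 over 5 genes (camera adjusted p = 0.206), with -0.16 without pair 2, -0.27 without AHSG and -0.28 without APOB.

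Counts adjusted over the list alone were 0 in each of the 7 lists, as were those over all probes. None of the lists was called by camera, by camera with an estimated correlation or by fry, and 1 had an unadjusted camera p under 0.05. The other lists had under 5 measured members, among them the thick and thin filament proteins of the sarcomere with 3 of 34 and fatty acid uptake and oxidation with 1 of 27.

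Among the heart and growth genes chosen in advance, NPPA, the atrial natriuretic peptide, was higher in IUGR by 0.76 ± 1.97, in 4 of 6 pairs (exact p = 0.469). Its level ran from 9.49 to 15.79 over the 12 hearts, and the mean difference ran from 0.27 without pair 3 to 1.37 without pair 1, with 0.50 without pair 5. The highest of these values lies close to the top of the scale, and the dimmest of its 6 probes, which reached 13.76, gave 1.05. MYH6, the alpha myosin heavy chain, differed by 0.21 ± 0.42 at a level of 14.98 ± 0.21 against 14.77 ± 0.24, by 0.07 without pair 2 and by 0.32 without pair 4. The troponins TNNC2 and TNNI2, members of the filament list named after their values were seen, differed by 0.02 ± 0.14 and -0.11 ± 1.18, the latter running from -0.31 without pair 3 to 0.34 without pair 1. TNNI2 is also a marker in the list for skeletal muscle fibres. Neither TNNC2 nor TNNI2 is among the cardiomyocyte markers. The troponins among those markers, TNNI3 and TNNT2, had no named probe, so no value is given for them. TNNC1, the other troponin C of the filament list, had none either. The values of TNNC2 and TNNI2 do not stand in for these genes. The only probes of MYH6 and TNNC2 lay at 14.38 to 15.27 and at 14.74 to 15.19, near the top of the scale. IGF1, the insulin-like growth factor, was lower, with a difference of -0.26 ± 0.67 and 5 of 5 probes of that sign. Its other 4 probes gave -0.47 to -0.58 and the mean of all 5 gave -0.49, while the value ran from -0.46 without pair 3 to -0.12 without pair 5 or 6. None passed the adjusted threshold in limma, and with the probe used each difference was smaller than its SD over the pairs. The unadjusted limma p of the 5 IGF1 probes ran from 0.0118 to 0.329, the highest being that of the probe used.

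**Figure D3:**
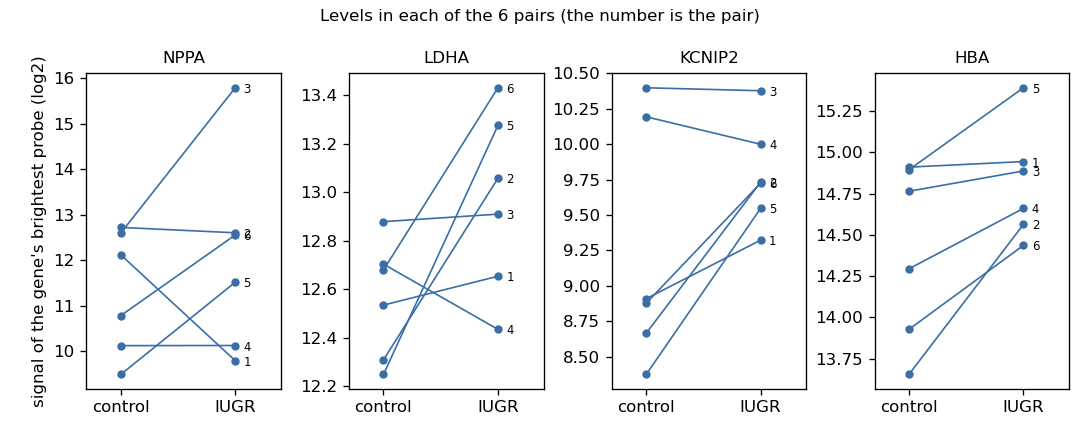
The vertical axes give the log2 signal of NPPA, LDHA, KCNIP2 and HBA in control and IUGR ventricles, on a separate scale for each gene, and each line joins the 2 samples of a pair. With the probe shown, HBA was higher in the IUGR sample of all 6 pairs, LDHA in 5, and NPPA and KCNIP2 in 4. Each of the dimmer HBA probes was higher in 5.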

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

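The signals of the genes and lists reported were screened with Dixon's test for a sample far from the other samples of its group, and 10 of 112 groups tested had one, where chance gives about 5.6. The genes outside the rule for named genes were added to the screen after their values had been seen. SLN, APOB, ITIH3, SERPINF2 and VTN are among them. The chance rate does not hold for their flags, so no excess is read from 10 against 5.6. TNFSF13B in IUGR replicate 1 stood at 4.29 log2, with the other IUGR samples from 2.33 to 2.91, and its mean difference was 0.34 without pair 1. SULT2A1 in IUGR replicate 5 stood at 5.51, with the others from 2.91 to 3.79, and its difference was 0.49 without pair 5. In control replicate 6, TREH stood at 4.10, with the others from 4.74 to 4.98, and CR1 at 5.68, with the others from 2.11 to 3.33. Without pair 6 the difference of CR1 was -0.39 and that of TREH -0.52. The mean of the cytokine and acute inflammation list in IUGR replicate 6 was 4.59, with the others from 5.09 to 5.38, and without pair 6 the list's mean difference turned from -0.07 to 0.05 and its adjusted p was 0.716. SLN in IUGR replicate 3, the heart with the highest NPPA, stood at 8.72, with the others from 4.83 to 5.94. APOB in control replicate 2 stood at 8.07, with the others from 2.04 to 2.82. In control replicate 6, the heart with the highest AHSG, ITIH3 stood at 7.12 (the others 2.34 to 3.41), SERPINF2 at 6.17 (3.04 to 4.03) and VTN at 5.08 (2.06 to 3.08).

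The comparisons with swapped labels were set in advance for the count of probes under an unadjusted p of 0.01 and extended to the calls, and they were run after the counts had been seen. With real counts of 0 probes past the adjusted threshold and 0 lists, each of the 32 ways to swap the labels within pairs had to give at least as many, so these counts of splits decide nothing; the highest of the other ways was 0 probes and 1 list. For the 224 probes at an unadjusted p under 0.01, 30 of the 32 ways gave at least as many, with a highest count of 441 in the others and a median of 305.5, so chance cannot be excluded. In addition, 100 splits of the 12 arrays, the real one included, were drawn without regard to the pairs and fitted without the block. The real split gave 111 probes. Counting the real one, 99 gave as many or more, and the highest gave 1862. The real split has 1 array of each pair in each group and so balances differences between pairs, which the others need not do. Its low count can therefore follow from the design, and this comparison decides nothing. Of the 100 splits, 6 called probes, up to 13 of them.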

How the results depend on the processing

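All alternatives were set in advance, but the intensity trend was carried into the list test only after the results of the other alternatives had been seen. In limma and in the ordinary paired test, no probe passed the adjusted threshold under any alternative run on the probes, also at 0.10 (lowest adjusted p = 0.897), and the fit without the paired block changed no call. The count at an unadjusted p under 0.01, 224, was 111 without the replicate block, 104 without the probes below the median level and 117 with an intensity trend and robust prior, ran from 192 to 317 when 1 pair was left out, and stayed within 1.5 times under the others. Dropping probes leaves fewer to be counted; the cause of the other shifts was not tested. The 0 lists called became 2 with the mean of all probes of a gene, 1 with the intensity trend, and from 0 to 2 when 1 pair was left out, with 2 only without pair 3; the cause was not tested. With an estimated correlation (lowest adjusted p = 0.347) and with fry (0.381), each run on the main settings only, no list was called. These calls were of glycolysis and glucose uptake in each case and of cytokines and acute inflammation besides, except with the trend; 5 of 122 list values passed. Of the 29 named genes, 25 kept their direction in all alternatives run for them, and 441 of 447 values did. The others were GNRHR (-0.06) and TNFSF13B (-0.01) with the mean of all probes, and, when 1 pair was left out, CKM from -0.05 to 0.03 and SLC2A1 from -0.08 to 0.12. Of 10 genes outside the rule, 2 turned direction when 1 pair was left out, ABCC9 from -0.04 to 0.07 and TNNI2 from -0.31 to 0.34. The p of the extracellular matrix list ran from 0.263 to 0.680 when 1 pair was left out, with a turned direction without pair 1. Without dim probes the hypoxia and liver or lung lists had under 5 members, and the dimmest named genes gave no value. No gene value passed the adjusted threshold. Dim probes limit the precision: the median standard error was 0.256 log2 below the median level.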

Other observations

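The genes in this part other than NPPA, HBA and AKR1D1 were singled out after their values were seen, and so were the comparison of array sets, the agreement between probes, the exact tests of AHSG and NPPA, the correlations of differences within pairs, those without control replicate 6 and the correlations within and between genes except those of NPPA with SLN and of AHSG with the liver genes. The list of smooth muscle and pericyte markers had 4 measured members and was not tested. TAGLN, transgelin, was higher in IUGR by 0.50 ± 0.43 (SD over 6 pairs) in 5 of 6 pairs, KCNJ8, a potassium channel subunit, by 0.15 ± 0.08 in 6 of 6, ABCC9, its partner, by 0.03 ± 0.19, turning to -0.04 without pair 5, and MYH11, the smooth muscle myosin, differed by -0.55 ± 0.92, by -0.87 without pair 3 and by -0.37 without pair 1, with its only probe at percentile 26.3 of the probe levels. COL8A1, a short-chain collagen, was lower in 5 of 6 pairs, with a difference of -0.39 ± 0.25. SLC6A8, the creatine transporter, was higher by 0.42 ± 0.52 in 5 of 6 pairs, and by 0.27 without pair 2. None of these passed the adjusted threshold in limma.

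HBB2, a beta chain of haemoglobin, was higher in IUGR by 0.12 ± 0.29 in 4 of 6 pairs, against 6 of 6 for the brightest HBA probe, and its difference ran from 0.07 without pair 3 to 0.33 with the mean of its 2 probes. The probe used lay at 15.26 to 15.78, close to the highest value of the table (15.83), and the other, at 9.80 to 11.89, gave 0.53. Over the 12 arrays HBA and the brighter HBB2 probe correlated at r = -0.256 (rho = -0.028, permutation p adjusted over 5 relations = 0.529 and 0.938), and r was 0.284 without the 2 samples farthest from the median of HBA. Their differences within the 6 pairs gave r = -0.924 and rho = -0.943 (exact p = 0.00278 and 0.0167, adjusted 0.00694 and 0.0417), but with the dimmer HBB2 probe r was 0.923 (exact p = 0.00972). Over the 3 probes of HBA, r ran from -0.924 to -0.686 with the brighter and from 0.616 to 0.960 with the dimmer HBB2 probe, so no relation is read from them. HBA and BPGM, the red cell enzyme that makes bisphosphoglycerate, correlated at r = 0.867 and rho = 0.832 (permutation p = 0.00018 and 0.00136, adjusted 9e-04 and 0.0068), with r = 0.844 without the 2 samples farthest from the median of HBA. Since the permutation treated the arrays of a pair as independent, its p-values can be too small. The differences within pairs of these 2 genes correlated at r = 0.370 and rho = 0.143 over 6 pairs (exact p = 0.479 and 0.803, adjusted 0.479 and 1), with r = -0.643 without the 2 pairs farthest from the median. The sets of 4 arrays described at the end are too small for a value within each.

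NPPA differed widely between hearts, with values from 9.49 to 15.79 log2. A faulty probe would make its 6 probes disagree, and the tables argue against it, since the lowest correlation between 2 of them over the 12 arrays was 0.993. Atrial tissue in some ventricle samples is a candidate explanation: SLN, sarcolipin, another atrial gene, correlated with NPPA at r = 0.67 (permutation p = 0.0219, adjusted 0.0548; rho = 0.301, p = 0.341, adjusted 0.568), but r was 0.040 without the 2 samples farthest from the median of NPPA, so over the arrays the relation rests on those samples. Here too the permutation ignored the pairs. The differences of NPPA and SLN within the 6 pairs correlated at r = 0.988 and rho = 0.943 (exact p = 0.00278 and 0.0167, adjusted 0.00694 and 0.0417), and at r = 0.960 without the 2 pairs farthest from the median, which is consistent with atrial tissue but also with any other joint control of these genes. GJA5, also atrial, gave r = 0.277 over the arrays (rho = 0.056, permutation p = 0.384 and 0.869, adjusted 0.529 and 0.938), -0.627 without the 2 samples, and r = 0.573 within pairs (rho = 0.486, exact p = 0.257 and 0.356, adjusted 0.428 and 0.593). NPPA also stands in the list for cardiac stress and the fetal programme, fixed in advance and not tested, with 3 measured members. A high NPPA signal alone is therefore no proof of atrial tissue. Growth restriction also stays open (exact p = 0.469 over the 64 sign changes of 6 pairs).

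AHSG, the fetal plasma protein fetuin-A, also differed widely, from 5.39 to 11.73 log2, and was lower in IUGR in 5 of 6 pairs with a difference of -1.13 ± 2.01, running from -1.88 without pair 3 to -0.75 without pair 1. A faulty probe is argued against by its 5 probes, whose lowest correlation was 0.991. RNA of fetal liver in some hearts would carry other liver genes along, and over the 4 of 19 such genes above the median level (HPX, ITIH4, C9 and AKR1D1, at 5.48, 6.47, 6.76 and 6.81 log2) the median correlation with AHSG was 0.089. That is below the bound of 0.2 set beforehand, but the test was judged unfit after its result had been seen, since the heart level of these 4 genes can hide a small share of liver RNA and C9 spanned only 0.84 log2 over the arrays. The other 15 genes, all dimmer, gave r from -0.266 to 0.792 with a median of 0.255, and the median over all 19 was 0.240. The highest were ITIH3 (0.792), SERPINF2 (0.695) and VTN (0.490), each with an outlying value in control replicate 6, the heart highest in AHSG. Without that array they gave 0.711, 0.489 and -0.061, and the median of the 15 was 0.047. Liver RNA stays open; APOB, which the marker list fixed in advance also holds, gave r = 0.020 and rho = 0.385 (permutation p adjusted = 0.962 and 0.554), and within pairs r = 0.285 (exact p = 0.456, adjusted 0.479), or 0.715 without 2 pairs, with 1 of its 3 probes of the sign of the probe used. Growth restriction stays open (exact p = 0.25 over the 64 sign changes of 6 pairs).

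Arrays of pairs 1 and 2, 3 and 4, and 5 and 6 resembled each other. The mean correlation of their deviations across pairs, 0.007, was rank 1 of the 15 ways to form 3 sets of 2 pairs, the next being -0.066. Arrays handled in 3 sets of 4 may give this, but 15 ways are too few for a share under 0.05 and no label names a set, so this cannot be told apart from litters or other shared features of the fetuses. Each set holds both groups, and the paired fit takes out differences in level between the sets. It does not take out IUGR minus control differences that vary between sets, such as those of KCNIP2. These were 0.74 in pairs 1 and 2, -0.11 in pairs 3 and 4, and 1.01 in pairs 5 and 6.

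Different probes of 1 gene agreed where the signal was high. For 179 genes with both of their brightest probes above the median level, the log2 differences of these probes correlated at 0.805 across genes and had the same sign in 81.0%. For 133 genes with both at or below it, the correlation was 0.0067 and 53.4% had the same sign. Genes are not independent replicates.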
